A study of Solanum tuberosum with 12 samples.

How the data were processed

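Small RNA was sequenced from tubers of 4 potato (Solanum tuberosum) cultivars, LK99, Longshu No.7, Red beauty and Black kingkong, with 3 libraries per cultivar and 12 libraries in all. Per the labels, the cultivars were planted together, grown under the same irrigation, light and temperature, and sampled at an age of 150 days. The small RNA fraction of 18 to 30 nt was cut from a gel and ligated to adapters, and PCR products of 140 to 160 bp were sequenced on a HiSeq 2500. The labels give no flesh or skin colour and do not say whether the libraries of a cultivar come from separate plants. The p-values therefore measure the spread between these libraries, which may be technical. The aligner, the counting program, the miRBase release and the genome build are not given in the sources used here, and no genome coordinates are given for any miRNA.

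The deposited table holds counts per mature miRNA and library, per the file headers; these are whole numbers without normalization, and the deposited total column equals their sum for 7827 of 7827 entries. A deposited length column gives a value in another unit (other), the length of each sequence in nt. A further deposited column per library, headed TPM in the file, was treated as a score: it equals the count divided by 1 number per library and put on 1 common scale, with zeros set to 0.01. That divisor was 79.0 (in 1e6 counts) for Black kingkong replicate 1, which is 11.9 times the total of its own counts, and 5.68 to 7.44 for the other libraries. These columns were used only in alternatives. Of the 7827 entries, 297 have a potato miRNA name, 935 a name from other species (written with the endings x, y or z) and 6595 were predicted by the authors. The entries hold 5730 distinct sequences of 18 to 26 nt, and 2097 entries repeat a sequence listed under another name. Entries with the same sequence need not have the same counts. Predicted miRNAs are identified here by their mature sequence. Entries that differ by a few bases were tested separately, so a higher and a lower entry can be variants of the same sequence.

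Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, limma 3.58.1, R 4.3.3) in 1 fit over the 12 libraries with 1 coefficient per cultivar. Entries were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 1349 entries with 1003 distinct sequences: 144 with potato names, 139 with names from other species and 1066 predicted. They held 99.8% of the counts in the median library. Library sizes were scaled by TMM factors, whose means were 0.986 in Black kingkong, 0.872 in Red beauty, 0.953 in Longshu No.7 and 1.24 in LK99. Levels are TMM-scaled CPM (counts per 1e6 counts), given as mean ± SD of 3 libraries. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons were any difference among the 4 cultivars, the 6 pairs of cultivars, the average of Black kingkong and Red beauty against the average of Longshu No.7 and LK99, and the miRNAs past the threshold with 1 sign in all 4 crosses of that split. Where a cultivar had 0 counts in its 3 libraries, the fold was computed against a floor of 3 counts over the cultivar and is given as "at least". With 1 to 3 counts the ratio is given with its 95% counting interval (exact binomial). Intervals and floors cover counting error only, since PCR copies of a read are not independent molecules.

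The fit was tested on simulated data with the counts of 1349 entries, 200 of them changed, in 10 simulations. It recovered 16% of the changes at 2-fold, 73.4% at 4-fold, 88.6% at 8-fold and 97.4% at 16-fold, and 3.50% of its calls were false. The depth was 5.61 to 7.35 (in 1e6 counts) per library. A count of 0 over the 3 libraries of a cultivar allows a level of up to 0.150 CPM in Black kingkong, 0.180 in Red beauty, 0.164 in Longshu No.7 and 0.131 in LK99.

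The design, the tests, 11 lists of miRNA families, the rule for naming miRNAs and the first set of alternatives were chosen before the data were examined. The lists were anthocyanin regulators of other plants (miR156, miR157, miR828, miR858), GAMYB and TCP regulators (miR159, miR319), auxin signalling (miR160, miR167, miR390, miR393), and meristem, leaf polarity and phase change (miR164, miR165, miR166, miR171, miR172, miR396). Further lists were copper-responsive miRNAs (miR397, miR398, miR408, miR857), phosphate, sulfate and nitrogen nutrition (miR395, miR399, miR827, miR2111, miR169), small RNA pathway targets (miR162, miR168, miR403) and resistance gene targets (miR472, miR482, miR1507, miR2109, miR2118, miR5300 and miR6019 to miR6027). The remaining lists were potato miRNAs of the number range miR7979 to miR8051, predicted miRNAs, and animal-type names as a marker of reads from other organisms. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry.

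In each pairwise comparison and in the average, the rule named the 5 highest and 5 lowest log2 fold changes among miRNAs past the threshold, with at least 10 CPM in the higher group and no overlap between the libraries of both sides. It also named up to 10 miRNAs per direction past the threshold in all 4 crosses, the most abundant entry of each family of a list (up to 4 per family for the anthocyanin list), and the 5 most abundant entries. Outside this rule, stu-miR530, miR530-x, stu-miR156e, stu-miR6149-5p, CTTGGCAACGATTTTTGTAGAA and ATCCAAAGGTTGTAGAAACTT were chosen after their values were seen. The text gives the members of this set that stand for a group, not each of them.

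The alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 test, no filter, a filter of 10 CPM in 3 libraries, the replicate number as a block, identical sequences merged, no predicted miRNAs, and limma-trend on the deposited score columns with a pseudocount of 1 or 0.1. Further alternatives were a fit of only the cultivars compared and leaving out each library in turn. For the lists they were an estimated correlation and counts summed per family. In fits with fewer libraries the filter was applied again, which changes the entries tested. Chosen after seeing the data were a table without miR166-y, a fit without the third libraries of Longshu No.7 and LK99, and the score column of Black kingkong replicate 1 recomputed with the median divisor of the other libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Target genes, anthocyanin contents and the paired transcriptome were not analysed here.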

Results

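The table gives counts of mature miRNAs in tubers of 4 potato cultivars at harvest, with 3 libraries each. Its stated subject is the miRNAs of anthocyanin synthesis and its regulation. In units of 1e6 counts, the libraries of Black kingkong held 6.62, 7.05 and 6.72, those of Red beauty 6.68, 5.61 and 6.92, those of Longshu No.7 7.35, 5.87 and 5.83, and those of LK99 6.03, 5.82 and 6.55. The miRNA miR166-y, of a family that targets HD-ZIP III transcription factors, took 87.4% ± 0.463 of the counts in Black kingkong, 91.7% ± 0.288 in Red beauty, 90.2% ± 0.579 in Longshu No.7 and 87.0% ± 1.34 in LK99 (SD, n = 3). Pearson's r of log2 CPM across tested miRNAs, which are not independent replicates, was 0.899 to 0.983 between libraries of 1 cultivar and 0.735 to 0.876 between cultivars. Within Longshu No.7 it was 0.899 to 0.982 and within LK99 0.931 to 0.973, and replicate 3 of each had the lower values.

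The first comparison asked which miRNAs differed among any of the cultivars. The miR858 family, which targets R2R3-MYB transcription factors in other plants, was abundant in Black kingkong and LK99 and low in Red beauty and Longshu No.7. Its main member miR858-x (TCTCATTGTCTGTTCGACCT) stood at 410 ± 79.1 CPM in Black kingkong and 189 ± 63.2 in LK99, against 2.07 ± 2.05 in Red beauty and 2.24 ± 2.00 in Longshu No.7 (adjusted p = 1.5e-06). The same cultivars were separated by stu-miR530, at 598 ± 32.4 and 806 ± 328 CPM against 14.3 ± 3.60 and 10.7 ± 4.52, and by stu-miR8006-5p, at 199 ± 15.5 and 103 ± 3.31 against 7.26 ± 1.66 and 6.32 ± 0.662. Red beauty stood apart by stu-miR156e, of the family that targets SPL transcription factors, at a mean of 132 CPM against 13.4 ± 7.46 in Black kingkong, 16.8 ± 2.83 in Longshu No.7 and 11.4 ± 4.40 in LK99. LK99 stood apart by low stu-miR6149-5p, which reached 994 ± 76.1 CPM in Black kingkong, 2039 ± 385 in Red beauty and 1053 ± 144 in Longshu No.7 (log2 fold changes over LK99 of 2.57, 3.60 and 2.65), and by stu-miR319a-3p, at 1393 ± 493 against 5566 ± 601, 2790 ± 605 and 4921 ± 887 in the same order.

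In the F-test, 794 of 1349 miRNAs (58.9%) differed among the cultivars, with 580 distinct sequences. Without a filter 1903 of 7827 passed, and with at least 10 CPM in 3 libraries 236 of 332 passed. The lists of animal-type names had 0 members in the table.

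**Figure D1:**
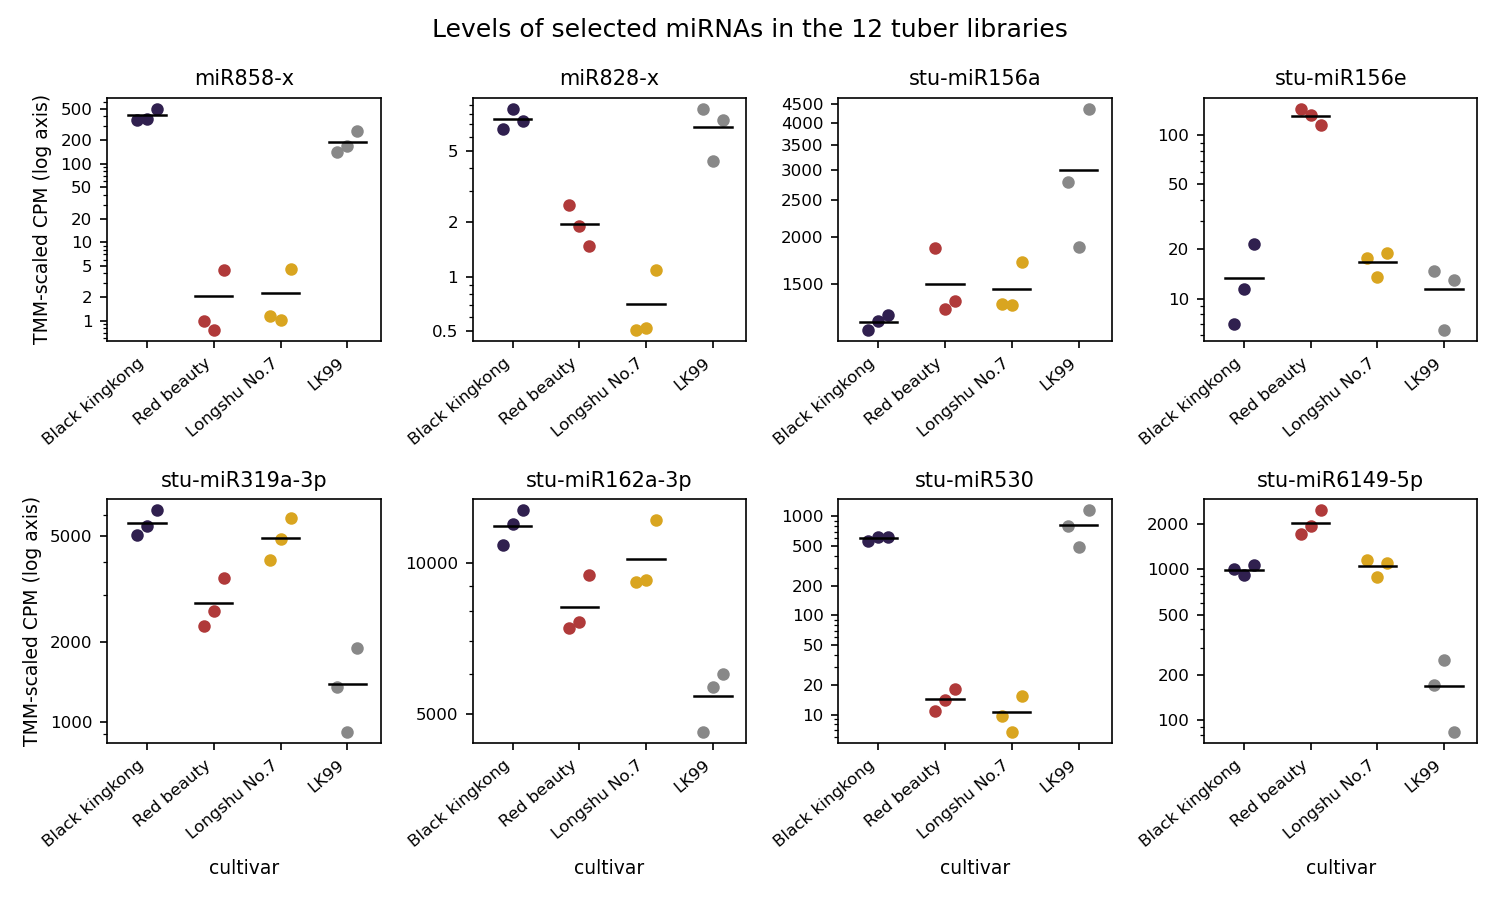
TMM-scaled CPM of 8 miRNAs (log axes) in each of the 12 libraries, grouped by cultivar, with points for libraries and a line for the mean of 3. The miRNAs miR858-x and stu-miR530 separate Black kingkong and LK99 from Red beauty and Longshu No.7, stu-miR156e is highest in Red beauty (132 CPM) and stu-miR6149-5p lowest in LK99.

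**Figure D2:**
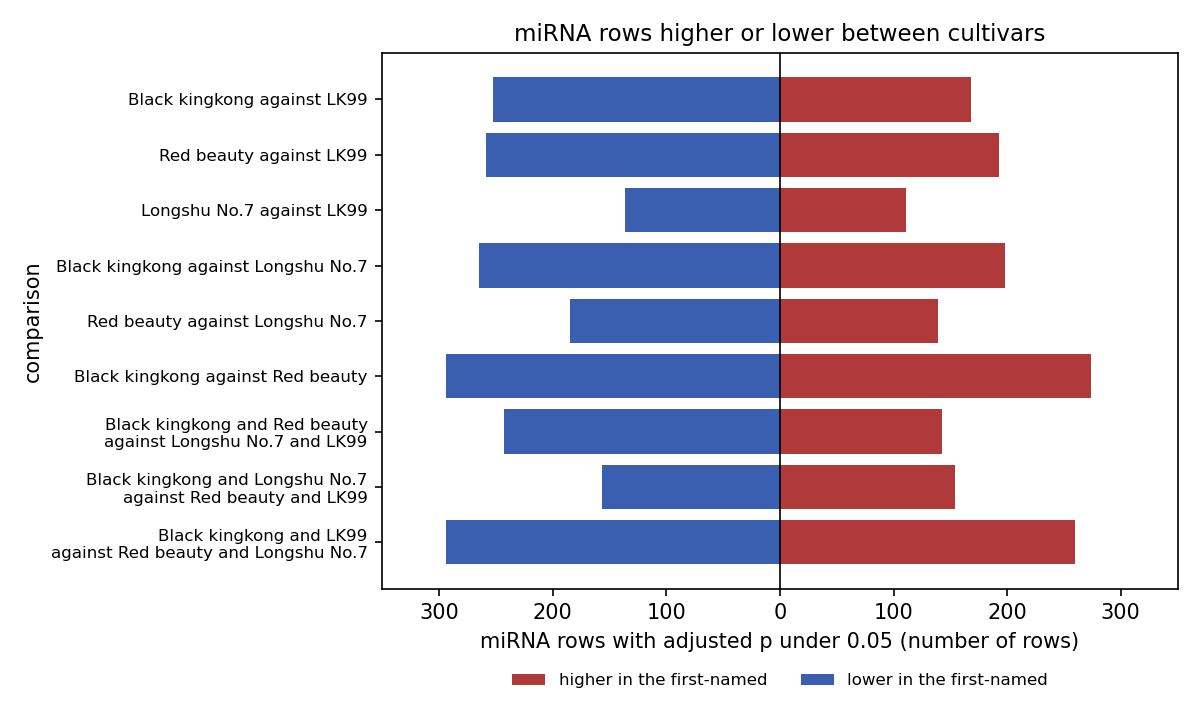
Number of miRNAs with adjusted p under 0.05 that were higher (bars to the right) or lower (bars to the left) in the cultivar or pair named first, for 6 pairwise comparisons and 3 ways of setting 2 cultivars against the others. The counts run from 247 for Longshu No.7 against LK99 to 568 for Black kingkong against Red beauty.

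Black kingkong against LK99 compared a dark-named cultivar with a cultivar whose name gives no colour. Black kingkong had more stu-miR319a-3p, which targets TCP transcription factors (log2 fold change 2.00, SE 0.27, adjusted p = 0.00014), and more stu-miR162a-3p, which targets DCL1 of the miRNA pathway (1.13, SE 0.19, adjusted p = 0.00075). It had less stu-miR156a, which targets SPL transcription factors: 1190 ± 55.3 CPM against 3014 ± 1261 (log2 fold change -1.34, SE 0.28, adjusted p = 0.0030). The R2R3-MYB regulators were counted in both cultivars: the rare miR858-z was higher in Black kingkong (2.89 ± 0.914 against 0.885 ± 0.149 CPM; 1.70, SE 0.50, adjusted p = 0.026). The main member miR858-x (1.12, SE 0.53, adjusted p = 0.13), miR858-y (0.62, SE 0.53, adjusted p = 0.41) and miR828-x (0.14, SE 0.35, adjusted p = 0.78) did not pass the test, but miR858-x did without Longshu No.7 replicate 3 (1.10, adjusted p = 0.029).

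Of the 20 tested anthocyanin regulators, 1 was higher and 8 were lower in Black kingkong, with the same counts adjusted over the list alone. The 8 hold 5 distinct sequences, since stu-miR156a to stu-miR156d share 1 sequence. The median of the list was 0.06 while camera pointed down (adjusted p = 0.32, and 0.69 with an estimated correlation). Of 7 GAMYB and TCP regulators 4 were higher and 0 lower, the same adjusted over the list alone. Camera called this list (adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.39). Small RNA pathway miRNAs were higher in 3 of 10 cases and lower in 0, unchanged when adjusted over the list alone. By family, 1 of 3 was higher and 0 lower, and stu-miR162a-3p and stu-miR162b-3p gave the same values. In this list miR168-x (0.36, SE 0.24, adjusted p = 0.27) and miR403-y (0.37, SE 0.21, adjusted p = 0.21) did not pass the test. The camera call (adjusted p = 0.025) had an adjusted p = 0.59 with an estimated correlation. Auxin miRNAs were higher in 4 of 12 cases and lower in 0, the same adjusted over the list alone. Among them stu-miR160a-5p, which targets auxin response factors, had 42 counts in Black kingkong and 3 in LK99, a ratio of 15.9 (5.09 to 80.4). Of 24 meristem and phase miRNAs 8 were higher (4 distinct sequences) and 0 lower, or 8 and 1 adjusted over the list alone, and of 5 copper-responsive miRNAs 2 were higher and 0 lower, in both adjustments.

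Among 24 nutrition miRNAs 5 were higher and 2 lower, or 10 and 3 adjusted over the list alone. The 5 hold 1 distinct sequence, and with counts summed per family 0 of 5 families were higher and 2 lower. The lower ones include miR2111-x (log2 fold change -2.79, SE 0.68, adjusted p = 0.0076) and stu-miR827-3p, which targets SPX-domain proteins of phosphate handling (-1.40, SE 0.38, adjusted p = 0.014). Of 25 miRNAs that target resistance genes 0 were higher and 4 lower, the same adjusted over the list alone. They include stu-miR6024-3p (-1.87, SE 0.47, adjusted p = 0.0088, and -1.09 without LK99 replicate 1) and the rare arm stu-miR6026-5p, which had 0 counts in Black kingkong against 161 in LK99 and was at least 47.1-fold lower. The abundant arm stu-miR6026-3p did not pass the test (-0.10, SE 0.21, adjusted p = 0.72). Of 77 miRNAs of the potato number range 3 were higher and 1 lower, or 2 and 1 adjusted over the list alone; stu-miR8033-5p was higher by 1.53 (SE 0.36, adjusted p = 0.0059).

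Predicted miRNAs were higher in 127 and lower in 232 of 1066 cases, or 129 and 233 adjusted over the list alone. The camera call of this list (adjusted p = 0.021, direction down) had an adjusted p = 0.39 with an estimated correlation. The sequence given below with 0 counts in Black kingkong and 230 in LK99 differs by 1 base from another entry. That other entry was higher in Black kingkong (log2 fold change 1.51, SE 0.26, adjusted p = 0.00077). Whether both are variants of the same sequence was not tested. The largest difference by the naming rule towards Black kingkong was that of TTTCAGAACCAGTAGCACTCA, with 47.8 ± 1.21 CPM against 0.216 ± 0.0616 (log2 fold change 7.65, SE 0.58, adjusted p = 6.0e-07). TCCATCAGCAGCAGAAGCTTT (5.33, SE 0.55, and 4.73 without LK99 replicate 2 or 6.33 without replicate 3) was also higher, GCTTAGATATGACATAGGGCT was lower (-6.43, SE 0.57, and -7.88 without Black kingkong replicate 1), and CTCAATCGGCAAGTAAACACT, with 0 counts in Black kingkong and 230 in LK99, was at least 67.4-fold lower.

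In all, 421 of 1349 miRNAs differed, 39.9% of them higher and 253 lower in Black kingkong, with 296 distinct sequences. In this and the 5 other pairwise comparisons, no library of 1 cultivar overlapped the other in any miRNA named as higher or lower. The exception was stu-miR827-3p between Red beauty and Longshu No.7. The naming rule asked for this separation in the largest differences, and the others are named because they passed the test. It is therefore no further support. Without such a choice, chance gives this separation in 10% of cases with 3 against 3. With library size alone the split was 108 higher and 326 lower, since the median log2 fold change moved by -0.33. The call of stu-miR6024-3p was lost without LK99 replicate 1 (adjusted p = 0.068) and that of stu-miR827-3p without Black kingkong replicate 1 or LK99 replicate 1 (adjusted p = 0.057 to 0.061).

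Red beauty against LK99 showed the low level of the R2R3-MYB regulators in Red beauty. The log2 fold change was -6.51 for miR858-x (SE 0.69, adjusted p = 2.1e-05, and -7.78 without Red beauty replicate 3, which held 24 of its 34 counts there) and -1.78 for miR828-x (SE 0.39, adjusted p = 0.0032). The SPL regulators went both ways by sequence: stu-miR156e was higher in Red beauty by 3.53 (SE 0.43, adjusted p = 4.7e-05), while the more abundant stu-miR156a was lower by 1.00 (SE 0.28, adjusted p = 0.013). Also higher was stu-miR6149-5p (3.60, SE 0.35, adjusted p = 1.2e-05), and stu-miR530 was lower (-5.82, SE 0.42, adjusted p = 1.8e-06).

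Of the 20 anthocyanin regulators 7 were higher and 9 lower in Red beauty, or 7 and 11 adjusted over the list alone. By distinct sequence 2 were higher and 6 lower, since stu-miR156e shares its sequence with 5 other entries. The median lay 1.00 below 0 while camera pointed up (adjusted p = 0.88, and 0.98 with an estimated correlation). Resistance gene miRNAs were higher in 1 and lower in 10 of 25 cases, or 1 and 12 adjusted over the list alone (camera adjusted p = 0.27). Among the lower ones, stu-miR6024-3p had a log2 fold change of -1.85 (SE 0.47, adjusted p = 0.0081, and -1.15 without LK99 replicate 1), and the rare arm stu-miR6026-5p had 1 count in Red beauty against 161 in LK99, a ratio of 117 (20.8 to 4661) towards LK99. The abundant stu-miR6026-3p did not pass the main test (-0.56, SE 0.21, adjusted p = 0.052) but passed in other settings, such as the DESeq2 test (-0.62, adjusted p = 0.0050). The meristem and phase miRNAs were higher in 6 and lower in 7 of 24 cases, the same adjusted over the list alone. Of 7 GAMYB and TCP regulators 3 were higher and 1 lower, or 3 and 2 adjusted over the list alone. They go apart by target: stu-miR319a-3p was higher (1.00, SE 0.27, adjusted p = 0.011) and miR159-y, which targets GAMYB factors, lower (-0.91, SE 0.25, adjusted p = 0.013).

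In the nutrition list 0 were higher and 2 lower of 24, in both adjustments; stu-miR169f-3p, of a family that targets NF-YA factors, had -2.24 (SE 0.43, adjusted p = 0.0013) and miR2111-x -4.02 (SE 0.81, adjusted p = 0.0019, and -3.42 without Red beauty replicate 1 or -5.36 without replicate 3). Potato-range miRNAs were higher in 2 and lower in 6 of 77 cases, or 2 and 4 adjusted over the list alone, with stu-miR8006-5p at -3.82 (SE 0.26, adjusted p = 1.8e-06) and stu-miR8036-3p at -1.01 (SE 0.21, adjusted p = 0.0022). Auxin miRNAs were higher in 1 and lower in 1 of 12, or 1 and 0 adjusted over the list alone. Copper-responsive miRNAs were higher in 1 of 5 and small RNA pathway miRNAs in 2 of 10, with 0 lower in each and no change when adjusted over the list alone. No list passed camera here. Predicted miRNAs were higher in 155 and lower in 218 cases, and adjusted over the list alone 2 more were higher. The abundant TGAAGGTCCGAGGTTGAGGTT was lower (80.2 ± 87.2 against 10071 ± 3022 CPM; log2 fold change -6.97, SE 1.06, adjusted p = 0.00029, and -8.32 without Red beauty replicate 3). GTGTGTCTCCTGTACCCTCCCT, with 344 counts in Red beauty and 0 in LK99, was at least 157.4-fold higher.

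In all, 452 miRNAs differed, 193 higher and 259 lower in Red beauty, with 331 distinct sequences. The split was 111 and 381 with library size alone, a median shift of -0.51. With the filter applied again, the count was 680 without Longshu No.7 replicate 3. The call of stu-miR319a-3p was lost without Red beauty replicate 3 or LK99 replicate 2 (adjusted p = 0.051 to 0.069), with library size alone (0.48, adjusted p = 0.10) and with no filter (adjusted p = 0.052) or with only these cultivars in the fit (adjusted p = 0.054), and that of miR159-y without Red beauty replicate 1 (adjusted p = 0.054).

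Longshu No.7 against LK99 had lower R2R3-MYB regulators on the side of Longshu No.7. The log2 fold change was -6.46 for miR858-x (SE 0.69, adjusted p = 3.2e-05, and -7.42 without Longshu No.7 replicate 3, which held 21 of its 36 counts there) and -3.30 for miR828-x (SE 0.44, adjusted p = 0.00017). Also lower were stu-miR530 (-6.24, SE 0.43, adjusted p = 9.5e-07), stu-miR8006-5p (-4.01, SE 0.27) and stu-miR156a (-1.05, SE 0.28, adjusted p = 0.018). Higher in Longshu No.7 were stu-miR319a-3p (1.82, SE 0.27, adjusted p = 0.00046), stu-miR162a-3p (0.91, SE 0.19, adjusted p = 0.0043) and stu-miR6149-5p (2.65, SE 0.34, adjusted p = 0.00012).

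Of the 20 anthocyanin regulators 0 were higher and 8 lower, or 0 and 10 adjusted over the list alone, with 5 distinct sequences among the 8. The camera call (adjusted p = 0.014) had an adjusted p = 0.77 with an estimated correlation. The GAMYB and TCP regulators were higher in 3 and lower in 0 of 7 cases, the same adjusted over the list alone, with the same camera values in the other direction (adjusted p = 0.014, and 0.77 with an estimated correlation). Small RNA pathway miRNAs were higher in 4 and lower in 0 of 10 cases, or 6 and 0 adjusted over the list alone, and camera gave an adjusted p = 0.052. By family, 1 of 3 was higher and 0 lower. The nutrition list had 1 higher and 2 lower of 24 in both adjustments; stu-miR169f-3p was lower (-2.19, SE 0.42, adjusted p = 0.0027), as was miR399-y, which targets the PHO2 regulator of phosphate uptake (-2.13, SE 0.63, adjusted p = 0.030). Resistance gene miRNAs were higher in 2 and lower in 3 of 25 cases, in both adjustments, with miR6027-x higher by 1.29 (SE 0.36, adjusted p = 0.022).

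Of the 77 potato-range miRNAs 1 was higher and 7 lower, or 1 and 3 adjusted over the list alone, with a median of 0.14 while camera pointed down (adjusted p = 0.79, and 0.85 with an estimated correlation). Of 12 auxin miRNAs 0 were higher and 1 lower, or 0 and 0 adjusted over the list alone. Meristem and phase miRNAs were higher in 2 of 24 (median -0.02, camera up) and copper-responsive miRNAs in 1 of 5, with 0 lower, the same adjusted over the list alone. Of the predicted miRNAs 83 were higher and 111 lower, in both adjustments. TGAAGGTCCGAGGTTGAGGTT (-8.52, SE 1.13) and AACTTTTCCAGGATTTGACCC (-8.75, SE 0.94) were lower, and CCTCAACTCGTCTCTACTGTGT, with 0 counts against 734 in LK99, was at least 196-fold lower. TATCTGAGTAGCATAGGGAATT (7.11, SE 1.06, adjusted p = 0.00046) was higher, by 6.23 without Longshu No.7 replicate 3 and 6.49 without LK99 replicate 1; its 6 counts in LK99 all came from replicate 3.

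In all, 247 miRNAs differed, 111 higher and 136 lower in Longshu No.7, with 182 distinct sequences. The split was 85 and 203 with library size alone (median shift -0.36). With the filter applied again, the count was 381 without Longshu No.7 replicate 3 and 414 without replicate 3 of both cultivars. It was 111 with only these cultivars in the fit. Calls lost in some settings were those of stu-miR156a without Longshu No.7 replicate 1, Longshu No.7 replicate 2 or LK99 replicate 3 (adjusted p = 0.055 to 0.064) or with only these cultivars in the fit (0.10), miR6027-x without LK99 replicate 1 (0.085), with library size alone (0.056) or only these cultivars (0.081), miR399-y without Longshu No.7 replicate 1 or LK99 replicate 3 (0.066 to 0.097), with a replicate block (0.054) or without replicate 3 of both (0.052), and stu-miR162a-3p with no filter (0.074).

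Black kingkong against Longshu No.7 set the R2R3-MYB regulators of Black kingkong against the low levels of Longshu No.7. The log2 fold change was 7.57 for miR858-x (SE 0.72, adjusted p = 4.3e-06, and 8.51 without Longshu No.7 replicate 3) and 3.44 for miR828-x (SE 0.44, adjusted p = 7.8e-05), and miR858-z, with 59 counts against 0, was at least 18.0-fold higher. Higher as well were stu-miR530 (5.81, SE 0.42), stu-miR8006-5p (4.96, SE 0.28) and stu-miR172a-3p, which targets AP2-like factors (0.87, SE 0.22, adjusted p = 0.0083). Lower in Black kingkong were stu-miR396-5p, which targets growth-regulating factors (5519 ± 601 against 13205 ± 5861 CPM; -1.26, SE 0.28, adjusted p = 0.0044), and stu-miR827-3p (-2.07, SE 0.39, adjusted p = 0.0013).

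Of the 20 anthocyanin regulators 4 were higher and 1 lower, the same adjusted over the list alone; the median was -0.31 while camera pointed up (adjusted p = 0.48, and 1.00 with an estimated correlation). For stu-miR156a the log2 fold change was -0.29 (SE 0.28, adjusted p = 0.44). Of 24 nutrition miRNAs 12 were higher (3 distinct sequences) and 3 lower, in both adjustments. The camera call (adjusted p = 0.0076) had an adjusted p = 0.39 with an estimated correlation, and it rests on the sulfate-responsive stu-miR395a, whose sequence stands under 10 names (3.34, SE 0.84, adjusted p = 0.0083, and 4.32 without Longshu No.7 replicate 1): with distinct sequences the adjusted p was 0.90. Also in this list, stu-miR169f-3p was higher (2.18, SE 0.42, adjusted p = 0.0017). Meristem and phase miRNAs were higher in 8 and lower in 3 of 24 cases and auxin miRNAs higher in 4 and lower in 0 of 12, both unchanged when adjusted over the list alone; stu-miR160a-5p had 42 counts against 3, a ratio of 12.8 (4.09 to 64.5).

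Resistance gene miRNAs were higher in 3 and lower in 4 of 25 cases, or 1 and 3 adjusted over the list alone, with miR6027-x lower (-1.35, SE 0.36, adjusted p = 0.011). Potato-range miRNAs were higher in 9 and lower in 9 of 77 (9 and 3 distinct sequences), or 8 and 8 adjusted over the list alone, with stu-miR8044-5p higher (3.35, SE 0.71, adjusted p = 0.0033, and 4.08 without Longshu No.7 replicate 2), which had 35, 40 and 0 counts in Longshu No.7. GAMYB and TCP regulators were higher in 1 and lower in 1 of 7 and small RNA pathway miRNAs higher in 1 and lower in 0 of 10, in both adjustments. Copper-responsive miRNAs were higher in 0 and lower in 1 of 5, or 0 and 0 adjusted over the list alone, with a median of -0.30 while camera pointed up (adjusted p = 0.99). Of the predicted miRNAs 148 were higher and 236 lower, or 148 and 238 adjusted over the list alone; TGAAGGTCCGAGGTTGAGGTT was higher (9.41, SE 1.18, adjusted p = 6.5e-05) and GCTTAGATATGACATAGGGCT lower (-6.98, SE 0.58, adjusted p = 8.9e-07, and -8.43 without Black kingkong replicate 1).

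In all, 463 miRNAs differed, 198 higher and 265 lower in Black kingkong, with 330 distinct sequences. The call of miR6027-x was lost without Black kingkong replicate 2 (adjusted p = 0.052).

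Red beauty against Longshu No.7 compared the cultivars in which miR858 was low, and miR858-x gave a log2 fold change of -0.05 (SE 0.67, adjusted p = 0.98). Red beauty had more stu-miR156e (2.97, SE 0.42, adjusted p = 0.00027) and more stu-miR6022, which targets receptor-like proteins of resistance (391 ± 33.7 CPM in Red beauty; 1.21, SE 0.21, adjusted p = 0.0011). It also had more stu-miR7992-5p (1.51, SE 0.36, adjusted p = 0.0087) and stu-miR395a (3.23, SE 0.86, adjusted p = 0.015, and 4.22 without Longshu No.7 replicate 1), and less stu-miR319a-3p (-0.82, SE 0.27, adjusted p = 0.039) and stu-miR827-3p (-1.30, SE 0.38, adjusted p = 0.025).

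The anthocyanin regulators were higher in 8 and lower in 0 of 20 cases, the same adjusted over the list alone, with 3 distinct sequences among the 8. Camera called this list (adjusted p = 0.0036) but not with an estimated correlation (adjusted p = 0.85). Besides stu-miR156e, miR828-x was higher (1.53, SE 0.47, adjusted p = 0.031), while stu-miR156a gave 0.05 (SE 0.28, adjusted p = 0.94). Summed over the family, miR828 was rare, at 2.03 ± 0.574 CPM in Red beauty and 0.774 ± 0.411 in Longshu No.7. Of 24 nutrition miRNAs 10 were higher and 1 lower, or 10 and 3 adjusted over the list alone; the 10 are the names of 1 miR395 sequence. Its camera call (adjusted p = 0.0036) had an adjusted p = 0.65 with an estimated correlation and 0.96 with distinct sequences. GAMYB and TCP regulators were higher in 0 and lower in 4 of 7, or 0 and 6 adjusted over the list alone. Meristem and phase miRNAs were higher in 1 and lower in 4 of 24, or 0 and 4 adjusted over the list alone.

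Resistance gene miRNAs were higher in 1 and lower in 3 of 25, copper-responsive miRNAs lower in 1 of 5, small RNA pathway miRNAs lower in 2 of 10 and auxin miRNAs called in 0 of 12, each the same adjusted over the list alone. Potato-range miRNAs were higher in 5 and lower in 8 of 77, or 4 and 4 adjusted over the list alone (median -0.02, camera up), with stu-miR8044-5p higher (3.08, SE 0.71, adjusted p = 0.0063, and 3.73 without Longshu No.7 replicate 2). Predicted miRNAs were higher in 111 and lower in 158 cases, and adjusted over the list alone 2 more were higher and 1 more lower. TTTGTCACGACCCGAGAGTACC was higher (5.76, SE 0.58, adjusted p = 0.00012, and 7.09 without Longshu No.7 replicate 1) and TTTTGTATGACTCACTCGGGAA lower (-5.73, SE 0.72, adjusted p = 0.00021, and -4.53 without Longshu No.7 replicate 3). TTTCATCGTTTAGAGCGTTCCT, with 0 counts in Red beauty and 112 in Longshu No.7, was at least 33.9-fold lower, and GTGTGTCTCCTGTACCCTCCCT, with 344 counts against 2, had a ratio of 190 (52.1 to 1572).

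In all, 324 miRNAs differed, 139 higher and 185 lower in Red beauty, with 226 distinct sequences. With the filter applied again, the count was 529 without replicate 3 of Longshu No.7 and of LK99. It was 203 with only these cultivars in the fit. Several calls depended on 1 library: stu-miR395a without Red beauty replicate 2 or Longshu No.7 replicate 2 (adjusted p = 0.055 to 0.057), stu-miR319a-3p without Red beauty replicate 1, Red beauty replicate 2, Longshu No.7 replicate 2 or Longshu No.7 replicate 3 (0.055 to 0.14), miR828-x without replicate 1 or replicate 2 of either cultivar (0.071 to 0.14) or with no filter (0.12), and stu-miR827-3p without any library of Red beauty or without Longshu No.7 replicate 1 or replicate 2 (0.055 to 0.10), with at least 10 CPM in 3 libraries (0.054) or with only these cultivars (0.060).

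Black kingkong against Red beauty compared both cultivars whose names carry a colour and gave the largest count of the pairwise comparisons. Black kingkong had far more miR858-x (7.62, SE 0.72, adjusted p = 4.4e-06, and 8.89 without Red beauty replicate 3) and more miR828-x (1.92, SE 0.39, adjusted p = 0.0015), and less stu-miR156e (-3.31, SE 0.43, adjusted p = 6.0e-05). It also had more stu-miR530 (5.39, SE 0.41), stu-miR8006-5p (4.77, SE 0.28), miR159-y (1.17, SE 0.25, adjusted p = 0.0021) and stu-miR319a-3p (1.00, SE 0.27, adjusted p = 0.0086). Of the meristem and phase list, stu-miR396-5p was lower (-1.39, SE 0.28, adjusted p = 0.0015) and miR164-x, which targets NAC factors, higher (3.63, SE 0.67, adjusted p = 0.00099, and 4.22 without Red beauty replicate 1). Summed over the family, miR164 was rare, at 4.70 ± 1.65 CPM in Black kingkong and 0.491 ± 0.447 in Red beauty.

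Of the 20 anthocyanin regulators 4 were higher and 9 lower, the same adjusted over the list alone, with 4 and 4 distinct sequences (camera adjusted p = 0.24). GAMYB and TCP regulators were higher in 5 and lower in 0 of 7, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.17). Meristem and phase miRNAs were higher in 11 and lower in 1 of 24 and auxin miRNAs higher in 5 and lower in 1 of 12, both the same adjusted over the list alone. Examples are stu-miR172a-3p (1.06, SE 0.22, adjusted p = 0.0018) and stu-miR160a-5p, with 42 counts against 2 and a ratio of 17.4 (4.53 to 148). Small RNA pathway miRNAs were higher in 4 and lower in 0 of 10, or 3 and 0 adjusted over the list alone. By family, 1 of 3 was higher and 0 lower. Resistance gene miRNAs were higher in 4 and lower in 2 of 25, or 3 and 1 adjusted over the list alone, with stu-miR482c higher (0.98, SE 0.25, adjusted p = 0.0063).

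Potato-range miRNAs were higher in 11 and lower in 10 of 77 (9 and 4 distinct sequences), or 9 and 9 adjusted over the list alone; stu-miR8033-5p was higher (1.92, SE 0.36, adjusted p = 0.0011) and stu-miR7992-5p lower (-1.55, SE 0.36, adjusted p = 0.0039). Nutrition miRNAs were higher in 1 and lower in 1 of 24, or 1 and 0 adjusted over the list alone, and copper-responsive miRNAs were called in 0 of 5 in both adjustments. No list passed camera. Predicted miRNAs were higher in 222 and lower in 261 cases, or 230 and 262 adjusted over the list alone. TGAAGGTCCGAGGTTGAGGTT was higher (7.86, SE 1.10, adjusted p = 0.00012, and 7.27 without Red beauty replicate 2 or 9.20 without replicate 3) and GTGTGTCTCCTGTACCCTCCCT, with 1 count in Black kingkong and 344 in Red beauty, had a ratio of 415 (74.0 to 16433) towards Red beauty.

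In all, 568 miRNAs differed, 274 higher and 294 lower in Black kingkong, with 430 distinct sequences. The larger side depends on the scaling: library size alone gave 308 higher and 257 lower (median shift 0.17), and DESeq2 size factors 290 and 284. The call of stu-miR482c was lost with predicted miRNAs left out (adjusted p = 0.057).

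The average of Black kingkong and Red beauty was set against the average of Longshu No.7 and LK99, since the series is about anthocyanin and the names of the first pair carry a colour. The R2R3-MYB regulator miR858-x did not differ on this split (0.53, SE 0.43, adjusted p = 0.37), as each side held a cultivar with it and a cultivar low in it. Higher on the side of the colour names were stu-miR395a (2.52, SE 0.55, adjusted p = 0.0037) and stu-miR166d-3p (0.62, SE 0.13, adjusted p = 0.0038). Lower were stu-miR827-3p (-1.35, SE 0.27, adjusted p = 0.0022), miR2111-x (-2.66, SE 0.56, adjusted p = 0.0031, and -3.31 without Red beauty replicate 3) and stu-miR156a (-0.65, SE 0.20, adjusted p = 0.025), whose levels overlapped between the sides. Against LK99 alone, stu-miR395a passed neither in Black kingkong (1.82, adjusted p = 0.057) nor in Red beauty (1.71, adjusted p = 0.074). Summed over the family, miR395 stood at 0.383 ± 0.336 CPM in Longshu No.7 and 1.24 ± 1.18 in LK99. Among predicted miRNAs, TTTGTCACGACCCGAGAGTACC was higher (4.94, SE 0.40, adjusted p = 1.4e-06, and 5.60 without Longshu No.7 replicate 1) and GCTTAGATATGACATAGGGCT lower (-4.97, SE 0.37, adjusted p = 1.1e-06, and -5.70 without Black kingkong replicate 1), without overlap.

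Of the 20 anthocyanin regulators 7 were higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.26). The higher ones include stu-miR156e (1.60, SE 0.29, adjusted p = 0.0010), which was high in Red beauty and not in Black kingkong, and miR828-x (0.83, SE 0.29, adjusted p = 0.048). The levels of both overlapped between the sides. With 1 entry per family, 0 of 4 anthocyanin families were higher and 1 was lower. Nutrition miRNAs were higher in 10 and lower in 2 of 24, or 10 and 3 adjusted over the list alone; the 10 are again 1 miR395 sequence. The camera call (adjusted p = 0.00093) had an adjusted p = 0.24 with an estimated correlation and 0.91 with distinct sequences. Predicted miRNAs were higher in 100 and lower in 218 cases, or 101 and 219 adjusted over the list alone, with a camera call (adjusted p = 0.019) that had an adjusted p = 0.24 with an estimated correlation. Resistance gene miRNAs were higher in 1 and lower in 6 of 25 and GAMYB and TCP regulators higher in 3 and lower in 0 of 7, each the same adjusted over the list alone. Potato-range miRNAs were higher in 6 and lower in 3 of 77, or 4 and 2 adjusted over the list alone. Meristem and phase miRNAs were higher in 4 and lower in 3 of 24 (median -0.01, camera up), small RNA pathway miRNAs higher in 3 and lower in 0 of 10, and the auxin and copper lists had 0 calls, all the same adjusted over the list alone.

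In all, 386 miRNAs differed, 143 higher and 243 lower, with 264 distinct sequences. Setting the other pairs against each other gave 311 (Black kingkong and Longshu No.7 against the others; 154 higher, 49.5% of the calls, or 110 higher of 275 with library size alone) and 554 (Black kingkong and LK99 against the others; 260 higher, 294 lower); the split by name lies between them. With 2 cultivars on each side these tests measure the spread between libraries within cultivars, not between cultivars of a colour; with library size alone the splits were 93 higher and 340 lower (median shift -0.24), and for Black kingkong and LK99 347 and 213 (0.28), or 267 and 264 with DESeq2 size factors. The call of miR828-x was lost without any 1 of 10 of the 12 libraries, all but Longshu No.7 replicate 3 and LK99 replicate 1 (adjusted p = 0.055 to 0.14), with library size alone (0.60, adjusted p = 0.15), the DESeq2 test (0.065), no filter (0.23), a replicate block (0.062), no predicted miRNAs (0.095) or no miR166-y (0.054), and that of stu-miR166d-3p with no filter (0.072).

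A stricter count took the miRNAs that passed in all 4 crosses of the colour-named cultivars with the others, in 1 direction. There were 47, of which 9 were higher and 38 lower in Black kingkong and Red beauty, with 28 distinct sequences. The rare arm stu-miR6026-5p is among the lower ones, while the abundant stu-miR6026-3p passed in 0 of the 4 crosses. The 5p arm had 0 counts in Black kingkong, 1 in Red beauty, 64 in Longshu No.7 and 161 in LK99. It was at least 23.3-fold lower in Black kingkong than in Longshu No.7, and its ratio of Longshu No.7 to Red beauty was 58.1 (10.1 to 2329). TATTAGAATCTGATAATAACT had 55 counts in Black kingkong and 36 in Red beauty and 0 in the others, so that it was at least 16.8-fold and 13.2-fold higher than in Longshu No.7. TGTACTCAGATTCTGCACTAGA, with 0 counts in both colour-named cultivars, 47 in Longshu No.7 and 105 in LK99, was at least 14.2-fold lower in each cross.

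Both other pairings gave 29 (16 higher, 13 lower, Black kingkong and Longshu No.7 against the others) and 57 (35 higher, 22 lower, Black kingkong and LK99 against the others). In 20 simulations without an effect the count was 0, and if the comparisons were independent 0.364 higher and 1.31 lower would be expected. Neither value tests the grouping by colour name. The simulations held no differences between cultivars, and the crosses share libraries. Among the pairings, the count of 47 lies between 29 and 57. With the filter applied again, the count was 75 without replicate 3 of Longshu No.7 and of LK99.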

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

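Of the settings, 3 were chosen after the results were seen: miR166-y left out, replicate 3 of Longshu No.7 and of LK99 left out, and the rescaled column of Black kingkong replicate 1. Counts follow the order of 4-cultivar test, Black kingkong against LK99, Red beauty against LK99, Longshu No.7 against LK99, Black kingkong against Longshu No.7, Red beauty against Longshu No.7, Black kingkong against Red beauty, average of the colour-named cultivars against the others, and all 4 crosses. The reference counts are 794, 421, 452, 247, 463, 324, 568, 386 and 47 of 1349 tested.

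With no filter the counts were 1903, 707, 950, 501, 831, 661, 1087, 682 and 91 of 7827. With at least 10 CPM in 3 libraries they were 236, 116, 153, 102, 140, 83, 183, 126 and 10 of 332. Without predicted miRNAs they were 134, 49, 71, 53, 77, 53, 73, 67 and 2 of 277. These settings change the number of entries tested. With identical sequences merged (1003 tested) the average gave 255 and the crosses 28.

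With replicate 3 of Longshu No.7 and of LK99 left out (1619 tested), Longshu No.7 against LK99 gave 414, Red beauty against Longshu No.7 529 and the crosses 75. With only the compared cultivars in the fit, Longshu No.7 against LK99 gave 111 and Red beauty against Longshu No.7 203. Limma on the deposited score columns with a pseudocount of 1 gave 208 for Black kingkong against Longshu No.7, 190 for Red beauty against Longshu No.7 and 313 for Black kingkong against Red beauty. With a pseudocount of 0.1 it gave 253, 202 and 346 for these, 278 for Red beauty against LK99 and 158 for Longshu No.7 against LK99. Once the column of Black kingkong replicate 1 was rescaled, every count was within 1.5 times the reference. So were all counts with DESeq2 size factors, library size alone, the DESeq2 test, miR166-y left out and a replicate block (773 for the 4-cultivar test). Of 18 pairs of libraries with the same number, 3 had a residual correlation over 0.1 (-0.0896 to 0.165), so not every pair passed 0.1 and no pairing is assumed. As a hint the other way, 8 of 12 libraries correlated best with their own number, and the mean was 0.0310 for the same number and -0.0147 for different numbers.

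Without each library in turn the counts ran from 810 to 1095, 304 to 615, 4.0e+02 (rounded) to 680, 182 to 381, 367 to 593, 223 to 461, 473 to 742, 350 to 523 and 35 to 66. Each highest count came without Longshu No.7 replicate 3. The filter was applied again each time, so the entries tested changed as well. A change in a count is therefore not the effect of the library alone. Of 432 calls of named miRNAs, 334 were kept without any 1 library.

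No call of a named miRNA turned into a call of the opposite sign, and changes of sign without that occurred in 3 settings. Limma on the score columns gave these values with a pseudocount of 1 and of 0.1. For Black kingkong against LK99 they were -0.77 and -0.77 for stu-miR166d-3p, -0.81 and -0.82 for stu-miR172a-3p, -0.36 and -0.36 for stu-miR162a-3p and stu-miR162b-3p, -0.52 and -0.54 for stu-miR8006-5p, and -0.39 and -0.58 for miR8019-y. For Black kingkong against Longshu No.7 they were -0.43 and -0.43 for stu-miR166d-3p, -0.19 and -0.20 for stu-miR172a-3p, -0.34 and -0.34 for miR403-y, -0.39 and -0.40 for stu-miR482c, -0.44 and -0.45 for stu-miR6022, and -0.43 and -0.44 for stu-miR8036-3p. For Black kingkong against Red beauty they were -0.0261 and -0.0266 for stu-miR319a-3p, -0.50 and -0.50 for stu-miR162a-3p and stu-miR162b-3p, -0.0632 and -0.0643 for stu-miR482c, and -0.0771 and -0.0886 for stu-miR8036-3p. For the average they were -0.14 and -0.14 for stu-miR166d-3p and for stu-miR319a-3p, -0.35 and -0.35 for stu-miR162a-3p and stu-miR162b-3p, -0.0506 and -0.0573 for stu-miR6022, -0.20 and -0.19 for stu-miR8006-5p, and -0.0732 with a pseudocount of 1 for miR828-x. None of these changed sign once the column of Black kingkong replicate 1 was rescaled. TCCTTGAACTCCATTTTAGCA, listed under 2 names, moved from 0.40 to -1.29 (adjusted p = 0.020) between Longshu No.7 and LK99 with replicate 3 of both left out.

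Among results for named miRNAs, those that stayed the same, were weaker or were stronger numbered 992, 3 and 6 with DESeq2 size factors, 955, 21 and 25 with the DESeq2 test, 924, 33 and 44 with library size alone, 916, 43 and 42 with no filter, and 970, 16 and 15 with a replicate block. They numbered 530, 4 and 12 with at least 10 CPM in 3 libraries, 993, 4 and 4 with merged sequences, 564, 20 and 11 without predicted miRNAs, 641, 31 and 27 with only the compared cultivars, and 956, 10 and 7 with miR166-y left out. Leaving out 1 library gave 11457, 426 and 129. Limma on the score columns gave 848, 112 and 17 with a pseudocount of 1 (24 reversed), 854, 111 and 13 with 0.1 (23 reversed), and 901, 54 and 46 with the rescaled column. Replicate 3 of Longshu No.7 and of LK99 left out gave 906, 14 and 72 (2 reversed).

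For the lists, camera at the preset correlation called 3 of 10 for Black kingkong against LK99, 2 for Longshu No.7 against LK99, 1 for Black kingkong against Longshu No.7, 2 for Red beauty against Longshu No.7 and 2 for the average, and 0 with an estimated correlation in every comparison. With merged sequences the adjusted p of the nutrition list was 0.90 for Black kingkong against Longshu No.7, 0.963 for Red beauty against Longshu No.7 and 0.913 for the average. Directional fry called 5, 1, 1, 4 and 3 of these, 1 for Red beauty against LK99 and 2 for Black kingkong against Red beauty. Counts summed per family kept miR156 lower than in LK99, by -1.29 in Black kingkong (adjusted p = 0.0025), -0.86 in Red beauty (0.022) and -1.01 in Longshu No.7 (0.016), and miR319 higher, by 1.95, 0.93 and 1.75.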

Other observations

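The tests of the patterns below were chosen after the values were seen, except the other splits of the libraries, which were planned; the splits that keep cultivars whole were chosen afterwards. Outside miR166-y, the predicted miRNAs took 32.0% ± 1.99 of the counts in Black kingkong and 28.6% ± 0.879 in LK99, against 16.8% ± 1.18 in Red beauty and 13.7% ± 0.502 in Longshu No.7. Potato names took 39.4% ± 1.06, 40.1% ± 0.573, 53.6% ± 1.03 and 53.5% ± 0.801 in the same order. Much of this is TGAAGGTCCGAGGTTGAGGTT, at 18690 ± 4055 CPM in Black kingkong and 10071 ± 3022 in LK99, against 80.2 ± 87.2 in Red beauty and 27.5 ± 3.60 in Longshu No.7. Sequences of 21 nt took 71.0% ± 1.86 in Black kingkong, 71.7% ± 1.00 in Red beauty, 67.5% ± 5.29 in Longshu No.7 and 65.5% ± 1.56 in LK99.

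Some sequences were counted in 1 cultivar and low or absent in the others. In Red beauty these were TTTGTATGACTCACCCGAGAAA (24.4 ± 3.63 CPM) and GTGTGTCTCCTGTACCCTCCCT (20.8 ± 5.80), and in LK99 CCTCAACTCGTCTCTACTGTGT (33.0 ± 24.3) and TTAAGAAAAGACTCATTCATG (10.4 ± 9.32). In Longshu No.7 they were ATCCAAAGGTTGTAGAAACTT (447, 426 and 1 counts), TATCTGAGTAGCATAGGGAATT (39.1 CPM) and TTTTTGGAGAATCCGAGCAAC (11.1 CPM), and in Black kingkong there were 0. The first of these Red beauty sequences is near-identical (within 3 mismatches and an offset of 3 nt) to a predicted miRNA named above. That one had a log2 fold change of -5.73 for Red beauty against Longshu No.7. It stood at 0.485 CPM in Red beauty, 39.2 in Black kingkong, 26.7 in Longshu No.7 and 83.9 in LK99. Whether both are variants of the same sequence was not tested. The miRNA stu-miR530 separated the cultivars while miR530-x, of the same family, stood at 673 ± 138 CPM in Black kingkong, 666 ± 161 in Red beauty, 630 ± 154 in Longshu No.7 and 609 ± 194 in LK99 (adjusted p = 0.96 in the F-test).

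The first pattern is a set of 7 sequences present in Black kingkong and LK99 and low in Red beauty and Longshu No.7: stu-miR530, miR858-x, miR858-y, TGAAGGTCCGAGGTTGAGGTT, CATCATCCTCGTACCTTCATC, AACTTTTCCAGGATTTGACCC and AATTACATGGAGATTTTTCTG. Every other pair of cultivars had 0 such sequences. A sequence variant counted under another entry was tested by adding near-identical entries outside the 7. For stu-miR530 the log2 ratio moved from 6.15 to 1.32, and the lower 95% limit of the difference in mean log2 level was 0.83. The ratio also falls if the added entries do not differ between the cultivars, so its drop is no measure of the share of a variant. For miR858-x, miR858-y and AATTACATGGAGATTTTTCTG, with 1 such entry each, the lowest limit was 6.01. These values argue against a variant counted under another entry as the whole source for these 4. A variant without an entry of its own would not be seen by this test and stays open. The 3 others have no near-identical entry to add, so for them a variant cannot be told apart from a difference in level. With library size alone the lowest log2 fold change of the 7 was 6.12. They were chosen for a large difference, and the TMM factors ran only from 0.785 to 1.38. Leaving the scaling out could therefore not undo the difference, and this value is no separate test of scaling by a few abundant sequences. No biological explanation was tested.

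Low counts of these sequences in Red beauty and Longshu No.7 may be carry-over of reads between libraries at 1 rate per library, with TGAAGGTCCGAGGTTGAGGTT as the tracer. Reads include PCR copies, so the error was taken from the spread of the 6 libraries. The value is the mean log2 of the ratio to the tracer over the highest such ratio in a library of Black kingkong or LK99. For stu-miR530 it was 2.34 (95% interval 0.0246 to 4.65), with 6 of 6 libraries above 0. The lower limit fell below 0 without Red beauty replicate 1 (-0.30) or without Longshu No.7 replicate 1 (-0.60), replicate 2 (-0.55) or replicate 3 (-0.80). For miR858-x it was 1.33 (-0.60 to 3.26) and for miR858-y the interval was -0.34 to 3.34. For the 3 others the lowest limit was -2.59, and AACTTTTCCAGGATTTGACCC followed the tracer at a mean of -0.10 (-0.37 to 0.18) over the pooled ratio of Black kingkong and LK99. With these limits low expression cannot be told apart from carry-over for any of the 6.

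In replicate 3 of Longshu No.7, 10 of the compared sequences were lost that are abundant in the other libraries of the cultivar, among them stu-miR8044-3p (161, 115 and 1 counts) and CTTGGCAACGATTTTTGTAGAA (3089, 2385 and 7). A library of 1 of the 3 other cultivars under this label is argued against: its highest mean correlation with another cultivar was 0.0580 below that with its own (-0.0580). Sequences were called lost on levels scaled for depth, so this choice already set lower depth aside and left no separate test of it. The lowest count expected at this depth was 60.5. Against reads of other cultivars mixed into replicates 1 and 2, the share a lost sequence needs was at least 11.3 times the highest share that sequences of the donor allow. A label from outside the series and differences between plants stay open, and no biological explanation was tested.

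In replicate 3 of LK99, 11 of 184 compared sequences were lost, against 1 in Red beauty replicate 2 and 0 in the 9 libraries other than these and Longshu No.7 replicate 3. A correlation difference of -0.0690 argues against a library of another cultivar under this label. A needed share of 9.65 times the allowed one argues against mixed reads. The lowest expected count was 92.2, again set by the choice of lost sequences. In units of 1e6 counts this library held 6.55, against 6.03 and 5.82 in the other LK99 libraries. A label from outside the series and plant differences stay open here too, and no biological explanation was tested.

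Other splits of the libraries were counted. For the 6 pairwise comparisons only 10 splits exist, too few for a share under 0.05; 1 of 10, the real one, gave as many calls, with 421, 452, 247, 463, 324 and 568 calls in the order of the report and a highest other of 0. For the 4-cultivar test 1 of 100 splits, the real one, gave as many (794, highest other 72). Random groupings of single libraries thus gave fewer calls. As the libraries of a cultivar may be technical, chance differences between the plants sampled are not excluded. For the average (386) and the crosses (47) the real split was also 1 of 100, with highest others of 33 and 0, but these splits break up the cultivars and do not test the grouping by colour name. With cultivars kept whole there are 3 splits, too few for a share under 0.05; 2 of 3 gave as many, the real one included, with highest others of 554 and 57, both for Black kingkong and LK99 against the others.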
